A study of Danio rerio with 18 samples.

How the data were processed

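The series profiled histone H3 lysine 27 acetylation (H3K27ac), a chromatin mark of active enhancers and promoters, by chromatin immunoprecipitation and sequencing (ChIP-seq) in organs of adult male zebrafish of the AB strain. Per the labels' protocols, brain, heart and testis came from fish aged 10 months and a further set of hearts and intestines from fish aged 1 year. Each replicate pooled 12 brains, 20 hearts, 5 intestines or 8 testes. The 18 libraries were 9 of immunoprecipitated DNA and 9 of input DNA, with 2 of each kind for every tissue and age except the heart at 10 months, which had 1 of each. Chromatin was sheared to fragments of 175 bp in the 10-month samples and 200 bp in the 1-year samples. Age, fragment size and preparation therefore changed together and cannot be separated.

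The deposited data were 10 region lists, a super-enhancer list and a typical-enhancer list for each of 5 tissue and age sets, in coordinates of the zebrafish build Zv9. Super-enhancers are long stretches of clustered enhancers that together carry high H3K27ac, and typical enhancers are the remaining regions. The submitters' processing notes name CASAVA, Bowtie2 2.1.0, SAMtools 0.1.8, bedtools 2.24.0 and SICER 1.1, without their roles or order. The program that joined neighbouring enhancers, the super-enhancer threshold, the treatment of input DNA and the way replicates were combined are not given in the sources used here. Region starts lie on multiples of 200 bp, and neighbouring regions that were both joined from loci lay at least 12601 bp apart. The region names give the number of loci joined.

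The value deposited with each region is a signal that is never negative. In the 1-year lists it was, for every region, a whole multiple of the region's length after multiplication by 10000, so the deposited signal is a mean per base pair with 4 decimals times the length, a total over the region. No scaling between lists is stated, so signal was compared only within a list, except in a ratio of signal to the number in the region names. There is 1 list of each kind per set and no value per replicate, and depth is unknown because no read counts were used. Every interval and p-value below is over regions or chromosomes, not over animals, and does not cover the difference between fish.

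In the 10-month lists many regions share a name, and regions with the same name carry the same signal whatever their length. A region was said to have its own signal when the signal times 10000 was a whole multiple of its length, with no tolerance. Regions of equal length with the same signal cannot be told apart by this rule, so all of them count as having their own signal. Signal per base pair was compared only over such regions. All regions were kept as deposited in the other comparisons.

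Lengths, numbers of loci and signal per base pair of super-enhancers and typical enhancers were compared within each set by the difference of medians, with a two-sided permutation test of 100000 resamples and Benjamini-Hochberg adjustment over the 5 sets. A super-enhancer was counted as shared with another list when it overlapped a region there by at least 50% of the shorter region. Shares carry exact Clopper-Pearson 95% intervals and were tested one-sided against 1000 circular shifts of the regions within each chromosome, with adjustment over the 20 ordered pairs of lists. Chromosome lengths were taken as the highest end coordinate in any list. Base-pair likeness was the Jaccard index, the base pairs in both lists as a percentage of those in either. Its interval and the two-sided test of differences came from 1000 bootstrap draws of the 25 chromosomes, as did the interval of the share of base pairs that lie in an enhancer of another tissue. In that last comparison, in regions merged over tissues and in counts over the 3 other tissues, the heart at 1 year stood for heart. Merged regions were set against 100 circular shifts. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

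The steps were tested on simulated data. Simulated regions given the signal of a region of another length matched their own length in 0.0787% of 13972 cases. Exchanges between regions of equal length were left out, so this rate does not cover them. For the overlap of 10-month heart with intestine super-enhancers, independent simulated lists fell below 0.05 in 6% of 100 runs, and lists with 20% of regions planted fell below it in all 20 runs, with 18.5 percentage points recovered. Simulated 95% intervals of a Jaccard difference of 0 covered 0 in 95% of 100 runs. For testis region lengths, simulated lists of equal length fell below 0.05 in 1% of 100 runs, and lists 1.5 times as long did so in all 20 runs.

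Regions are named by a rule fixed before the data were examined. It takes the 10 super-enhancers of each set with the highest signal, the longest 10 regions with a super-enhancer in all 4 tissues, and up to 5 heart super-enhancers per direction without an enhancer in the other heart list. After the values were seen, the first part was limited to regions with their own signal, and regions without an enhancer in the other tissues were added. Coordinates count from 1. Gene annotation in Zv9 coordinates was not used here, so regions carry no gene names, and the planned test of tissue marker genes was not run. Alternatives changed the overlap needed, the super-enhancer threshold, the chance model, the typical enhancers compared and the list that stood for heart. Alternatives added after seeing the data kept only super-enhancers with their own signal, redrew super-enhancers as the longest regions, or ranked them by length.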

Results

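The lists held 3989 super-enhancers and 62317 typical enhancers on 25 chromosomes. They described brain, heart and testis of 10-month-old male zebrafish and heart and intestine of 1-year-old males. The study's title names a comparison of super-enhancers between vertebrates, of which the zebrafish lists are the part analysed here. The comparisons below ask how super-enhancers differ from typical enhancers in each tissue, how far they are shared between tissues, and how far the heart lists of both ages resemble each other.

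Super-enhancers were a small part of the enhancers of every tissue and a large part of their base pairs. The intestine had the most, 1145, followed by the heart at 1 year with 850, the heart at 10 months with 749, the brain with 664 and the testis with 581. Their share of all enhancer regions ran from 5.02% in the brain to 7.61% in the intestine, and their share of enhancer base pairs from 20.0% in the testis to 35.1% in the intestine. Super-enhancers covered 73.6 Mb in the heart at 1 year, 69.2 Mb in the intestine, 51.2 Mb in the brain, 39.0 Mb in the heart at 10 months and 12.1 Mb in the testis.

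The testis list stood apart in length. The median testis super-enhancer was 17.2 kb long and joined 2 loci, whereas the median was 67.0 kb and 9 loci in the brain, 47.4 kb and 8 loci in the heart at 10 months, 75.5 kb and 11 loci in the heart at 1 year, and 52.2 kb and 7 loci in the intestine. Super-enhancers of a single locus made up 19.6% of the testis list and 2.54% to 7.60% of the others. Typical enhancers had medians of 2.80 to 3.80 kb in the 5 sets, but their upper quartile was also lower in the testis, 5.20 kb against 9.80 to 13.8 kb in the others. Super-enhancers were longer than typical enhancers in all 5 sets, by 13.8 kb at the median in the testis and by 44.6 to 71.7 kb in the others (permutation test, adjusted p = 1e-05 in each set, the smallest that 100000 permutations can give). Since super-enhancers are clusters joined over long stretches, much of this difference follows from how such lists are made. Without replicate values the lengths of different tissues were not tested against each other.

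**Figure D1:**
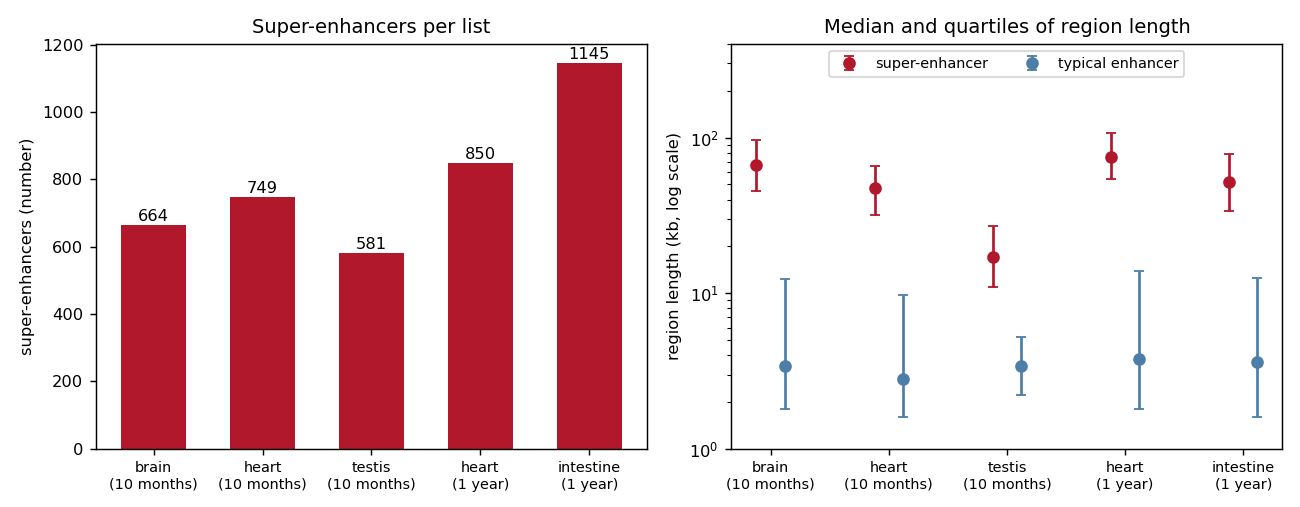
Left, the number of super-enhancers in each list. Right, the median length in kb (points, log scale) with quartiles (bars) of super-enhancers (red) and typical enhancers (blue); the testis super-enhancers, at 17.2 kb, lie below the 47.4 to 75.5 kb of the other lists, while typical enhancers lie between 2.80 and 3.80 kb in all.

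Signal per base pair was higher in super-enhancers than in typical enhancers of the intestine. The intestine median was 0.651 signal units per bp in super-enhancers and 0.560 in typical enhancers, and 70.3% of super-enhancers exceeded the typical median (permutation test, adjusted p = 2.5e-05). In the heart at 1 year the medians were 0.480 and 0.478 and did not differ past the threshold (permutation test, adjusted p = 0.850). The 10-month values cover only regions with their own signal, which left out 4.97% of super-enhancers and 61.3% of typical enhancers in the brain, 20.8% and 74.2% in the heart and 27.4% and 73.5% in the testis. Because the shares left out differ so much between the classes, no direction is read from these medians. They were 0.433 and 0.509 in the heart at 10 months (permutation test, adjusted p = 2.5e-05), 0.477 and 0.464 in the brain (permutation test, adjusted p = 0.137) and 0.396 and 0.407 in the testis (permutation test, adjusted p = 0.137). The signal did not order the lists by itself, since 1187 typical enhancers of the heart at 1 year and 1016 of the intestine carried more signal than the lowest super-enhancer of their set.

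The regions with the highest signal were mostly shared between heart and intestine. All 10 named super-enhancers of the heart at 1 year were also super-enhancers in the heart at 10 months and in the intestine, and 6 were super-enhancers in the brain. Over the whole list the shares in the heart at 10 months and in the intestine were 60.8% and 61.3%. The 10 named regions were 157 to 356 kb long against a list median of 75.5 kb, and longer regions overlap others more easily. The first was on chromosome 13 from 25058001 to 25413599 (356 kb, 51 loci, signal 193517), followed by chromosome 22 from 32735001 to 33060999 (326 kb, signal 176137). All 10 of the heart at 10 months were super-enhancers in the heart at 1 year and 9 were in the intestine. They were led by chromosome 8 from 21118001 to 21290999 (173 kb, 28 loci), a locus that was also among the named regions of the heart at 1 year and of the intestine. Of the 10 named intestine super-enhancers, 10 were super-enhancers in the heart at 1 year and 9 in the heart at 10 months. The first lay on chromosome 17 from 37833201 to 38097799 (265 kb, 29 loci, signal 198449) and had a typical enhancer in the brain and none in the testis.

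The brain and testis differed from this. Among the 10 named brain super-enhancers, 4 were super-enhancers in each heart list and 4 in the intestine. The brain region with the highest signal, chromosome 12 from 25849601 to 26145399 (296 kb, 30 loci, signal 174255), had no enhancer of either kind in any other list. The brain region that came next, chromosome 1 from 40724001 to 40966399 (242 kb, signal 163668), was a super-enhancer in all 5 lists. The named testis regions were 23.4 to 81.6 kb long, led by chromosome 12 from 28583201 to 28664799 (81.6 kb, 7 loci, signal 32444), which was a super-enhancer in the intestine and a typical enhancer in the brain and both hearts.

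**Figure D2:**
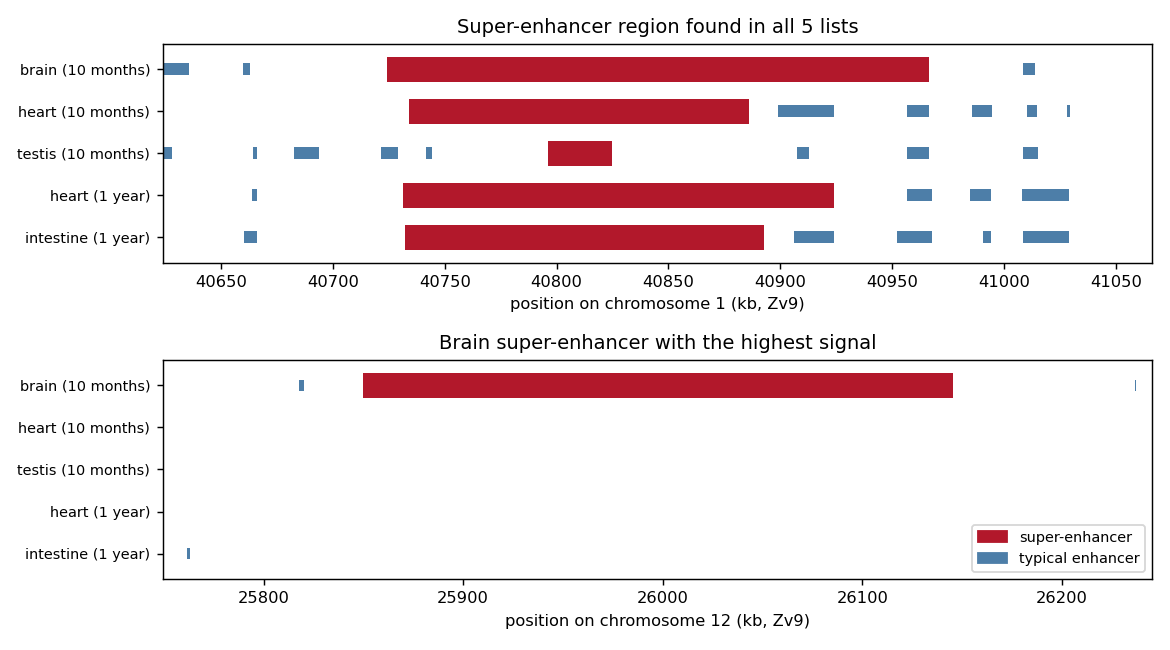
Enhancer regions of the 5 lists along 2 stretches of the genome (position in kb on Zv9; red, super-enhancers; blue, typical enhancers). The upper map shows chromosome 1 around 40724001 to 40966399, with a super-enhancer in every list; the lower map shows chromosome 12 around 25849601 to 26145399, where the brain super-enhancer has no counterpart in the other lists.

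Each list shared more super-enhancers with each other list than shifted positions did. The shared percentage was 3.24 to 12.1 times the mean of the shifts, and adjusted p was 0.000999 for all 20 ordered pairs, the smallest that 1000 shifts can give. The excess was far smaller when the super-enhancer label was drawn among enhancers of like length in the same list, with an observed percentage 1.16 to 1.65 times the mean of the draws. The enhancers drawn from included the super-enhancers themselves, which pulls that mean toward the observed percentage. For the heart at 10 months in the heart at 1 year that mean was 57.1%, and for the heart at 1 year in the intestine 41.8% (adjusted p for the 20 pairs 0.00111 to 0.012, one-sided permutation of labels). Like length meant the same of 5 classes, cut at quantiles of super-enhancer length. These classes are wide, and typical enhancers within a class may be shorter than its super-enhancers. The draws therefore cannot decide whether the remaining excess is due to length. Of the 749 super-enhancers of the heart at 10 months, 73.7% (95% interval 70.4 to 76.8) overlapped a super-enhancer of the heart at 1 year, 57.3% (53.6 to 60.9) one of the intestine, 19.6% (16.8 to 22.7) one of the brain and 16.3% (13.7 to 19.1) one of the testis. The shifted means were 6.10%, 6.38%, 4.28% and 2.35%. Of the 850 super-enhancers of the heart at 1 year, 60.8% (57.5 to 64.1) overlapped one of the heart at 10 months and 61.3% (57.9 to 64.6) one of the intestine. Brain super-enhancers were shared with the heart at 1 year in 27.1%, with the intestine in 25.5%, with the heart at 10 months in 21.4% and with the testis in 11.6%. Testis super-enhancers were shared with the intestine in 31.5% and with the brain in 13.6%.

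**Figure D3:**
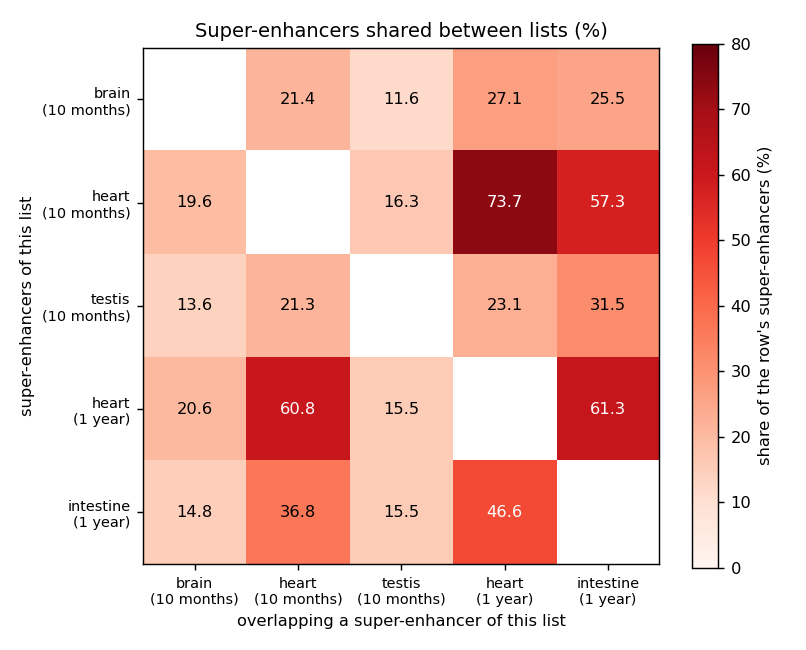
Percentage of the super-enhancers of each list (vertical axis) that overlap a super-enhancer of another list (horizontal axis) by at least 50% of the shorter region. The hearts and the intestine form the darkest block, from 36.8% to 73.7%, and every value involving brain or testis lies between 11.6% and 31.5%.

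In base pairs the heart lists had the highest likeness of all pairs, but their lead over the heart at 1 year and the intestine was lost under 3 alternatives. Heart super-enhancers had a Jaccard index of 37.7% (95% interval 34.6 to 40.2), against 32.2% for the heart at 1 year and the intestine, 24.2% for the heart at 10 months and the intestine, and 2.76% to 11.0% for the 7 pairs with brain or testis. The heart pair exceeded the heart at 1 year and the intestine by 5.42 percentage points (3.02 to 7.73) and all other pairs by more (adjusted p = 0.002 for all 9, n = 25 chromosomes, the smallest that 1000 bootstrap draws can give). A Jaccard index cannot exceed the base pairs of the smaller list over those of the larger. Testis super-enhancers covered 12.1 Mb and each other list at least 39.0 Mb, so no testis pair could have reached the heart pair. The difference of the heart pair to the heart at 1 year and the intestine was less stable. With only the upper part of each super-enhancer list, ranked by signal, that difference was 3.31 points (-0.135 to 6.94) and no longer past the threshold. It was 2.47 points (-1.39 to 6.33) with the upper part ranked by length and 1.32 points (-1.21 to 3.84) with the longest regions of each list taken as super-enhancers. Over all enhancers the heart pair reached 47.8%, against 44.0% for the heart at 1 year and the intestine.

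Nearly all super-enhancers of either heart list overlapped an enhancer of the other by at least 50% of the shorter region, but not always a super-enhancer. Of the super-enhancers of the heart at 10 months, 552 were super-enhancers in the heart at 1 year, 194 (25.9%) were typical enhancers there and 3 (0.401%) had no enhancer. With at least 50% of both regions required, 34.6% had none. Of those of the heart at 1 year, 517 were super-enhancers in the heart at 10 months, 332 (39.1%) were typical enhancers and 1 (0.118%) had none, or 45.4% under the reciprocal overlap. The typical state there is uncertain, since 74.2% of typical enhancers of the heart at 10 months lacked their own signal. Over all enhancers, 52.5% of the base pairs of the heart at 1 year lay in an enhancer of the heart at 10 months and 84.2% the other way. The 3 regions of the heart at 10 months were on chromosome 18, from 6243801 to 6253599, 23208201 to 23215399 and 25908401 to 25915799, and all carried the same signal, 10517, which did not match the length of any of them. That of the heart at 1 year was on chromosome 3 from 34827401 to 34839999 (12.6 kb) and was a super-enhancer in the intestine. Near-complete overlap was not particular to the heart pair. In the intestine, 21 (2.80%) super-enhancers of the heart at 10 months and 8 (0.941%) of the heart at 1 year had no enhancer. The shares without an enhancer were 16.8% and 13.4% in the brain and 26.6% and 21.2% in the testis.

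The share kept in the other heart exceeded the share found in another tissue for 5 of 6 comparisons. For the heart at 10 months the difference was 16.4 percentage points (12.5 to 19.9) against the intestine, 54.1 against the brain and 57.4 against the testis. For the heart at 1 year it was 40.2 points against the brain and 45.3 against the testis (adjusted p = 0.0024 for all 5, two-sided bootstrap, n = 25 chromosomes). Against the intestine it was -0.471 points (-5.34 to 3.59, adjusted p = 0.825, n = 25 chromosomes). Under a reciprocal overlap of 50% this last difference was -6.35 points (-10.6 to -2.52), with own signal only -7.18 (-11.5 to -3.40) and with the longest regions as super-enhancers -5.88 (-10.3 to -1.59), each with the larger share in the intestine. In this comparison the own-signal form took super-enhancers only from the heart at 10 months, so it could only lower the share in that heart. The differences make no allowance for shifted positions, whose mean shares were higher for the intestine. These were 2.86% against 1.71% for the heart at 10 months under reciprocal overlap, and 8.84% against 5.58% with the longest regions. The intestine and the heart at 1 year shared age, fragment size and preparation, and the hearts did not.

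Super-enhancers lay in enhancers of other tissues more than typical enhancers did, except in the brain. In the intestine 81.2% of super-enhancer base pairs and 65.5% of typical-enhancer base pairs lay in an enhancer of another tissue, a difference of 15.7 percentage points (14.3 to 17.1). The differences were 12.6 points (10.3 to 14.9) in the heart at 10 months, 11.8 (9.66 to 13.7) in the heart at 1 year and 9.45 (6.31 to 12.4) in the testis (two-sided bootstrap, adjusted p = 0.0025 for these 4, n = 25 chromosomes). In the brain the shares were 49.0% and 52.5%, so super-enhancers were lower by a difference of -3.48 points (-6.62 to -0.445, adjusted p = 0.028, n = 25 chromosomes). Each list was set against its own group of other tissues, so these values depend on which tissues were sampled. Over all enhancers the heart at 1 year and the intestine had a Jaccard index of 44.0%. The closest list to the brain, the heart at 1 year, reached 23.3%.

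**Figure D4:**
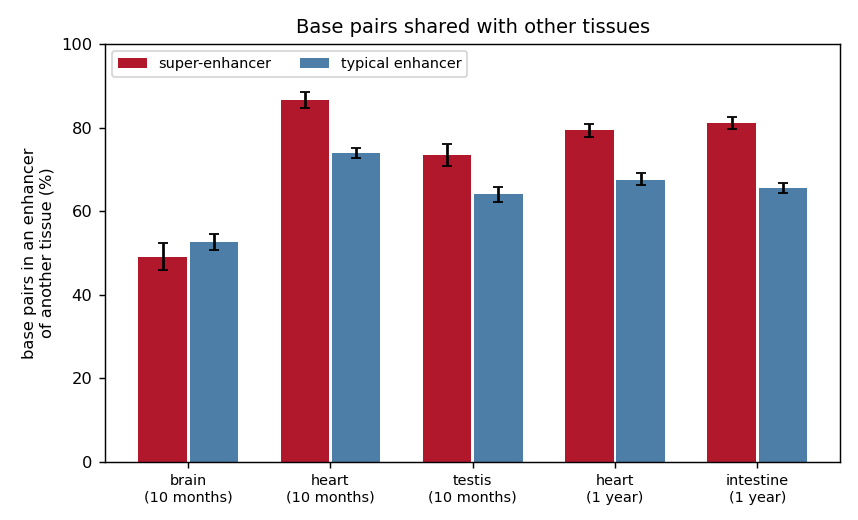
Percentage of super-enhancer (red) and typical-enhancer (blue) base pairs of each list that lie in an enhancer of another tissue, with 95% bootstrap intervals over chromosomes (bars). The brain, at 49.0% and 52.5%, has the lowest values and is the only list in which super-enhancers lie below typical enhancers.

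Super-enhancers without a super-enhancer in the 3 other tissues were most frequent in the brain, 66.1% (95% interval 62.4 to 69.7), and the testis, 59.7% (55.6 to 63.7). The values were 45.2% in the intestine, 34.7% in the heart at 10 months and 31.9% in the heart at 1 year. Super-enhancers without an enhancer of any kind in the 3 other tissues were rarer: 65 in the testis (11.2%), 56 in the brain (8.43%), 19 in the intestine (1.66%), 8 in the heart at 10 months (1.07%) and 0 of 850 in the heart at 1 year, for which the interval reaches 0.433%. For brain, testis and intestine the heart at 1 year stood for heart in these counts. Over all 4 other lists, 49 in the testis, 43 in the brain and 14 in the intestine had no enhancer elsewhere. In the brain, chromosome 5 from 68260601 to 68383599 (123 kb, 17 loci) was such a region, in the testis chromosome 5 from 26210001 to 26241199 (31.2 kb), and in the intestine chromosome 3 from 23978601 to 24006399 (27.8 kb, 1 locus, 1.52 signal units per bp). These 3 were chosen after their values were seen. Counts among super-enhancers with their own signal again took the heart at 1 year as heart for brain and testis. No enhancer in the 3 other tissues was found for 52 of 631 in the brain (8.24%, 6.22 to 10.7), 36 of 422 in the testis (8.53%, 6.05 to 11.6) and 0 of 593 in the heart at 10 months.

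Merging the super-enhancers of the 4 tissues gave 2188 regions, of which 1489 (68.1%) held super-enhancers of 1 tissue, 476 of 2, 166 of 3 and 57 of all 4. The shifted lists, which do not keep the positions of enhancers, gave means of 2590, 273, 24.6 and 1.11, with at most 4 regions in all 4 tissues. Heart with intestine was the most frequent combination, with 309 regions, followed by 87 for brain with heart and intestine, 68 for intestine with testis and 60 for heart with intestine and testis. Brain with heart had 34, brain with intestine 28, heart with testis 23 and brain with testis 14. Regions of a single tissue numbered 491 in the intestine, 411 in the brain, 328 in the testis and 259 in the heart.

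Of the 57 regions with super-enhancers in all 4 tissues, 48 also held one of the heart at 10 months and 48 contained base pairs common to all 4. The longest was on chromosome 18 from 7951001 to 8254599 (304 kb), where the heart at 10 months had no super-enhancer and the testis region lacked its own signal. The next were chromosome 19 from 36623001 to 36903199 (280 kb), chromosome 23 from 22941001 to 23215199 (274 kb), chromosome 4 from 7234401 to 7492599 (258 kb), chromosome 22 from 18842801 to 19089999 (247 kb) and chromosome 1 from 40724001 to 40966399 (242 kb). They were followed by chromosome 17 from 37455401 to 37684399, chromosome 25 from 35523001 to 35748799, chromosome 22 from 17055401 to 17277599 and chromosome 18 from 17440801 to 17651599, at 211 to 229 kb. The testis super-enhancer also lacked its own signal in the region on chromosome 23 and in that on chromosome 22 from 17055401. The latter, the region on chromosome 4 and that on chromosome 18 from 17440801 had 0 bp covered in all 4 tissues, so the super-enhancers there lie in a chain without a common stretch. Chromosome 25 had the longest stretch covered in all 4 tissues among these 10, 48 kb. With only the upper part of each list by signal, 10 regions held super-enhancers of all 4 tissues.

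**Figure D5:**
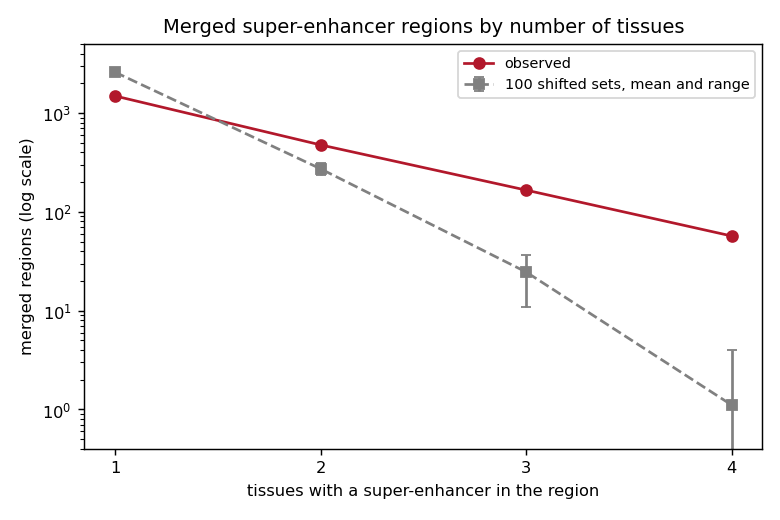
Merged super-enhancer regions (log scale) by the number of tissues with a super-enhancer in them, as observed (red) and in 100 sets of shifted lists (grey, mean and range). At 4 tissues 57 regions were observed against a mean of 1.11; the lower bar runs off the axis there because the lowest shifted count was 0.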

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

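Of the tests in this part, those of shared names, of matching lengths and of equal signal were chosen after the result was seen, and the test within length classes before.

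The contrast of super-enhancers with typical enhancers in their share of base pairs in other tissues' enhancers differed between tissues, by a bootstrap test of the difference itself over the 10 pairs of lists. The brain contrast lay below that of the heart at 10 months by a difference of -16.1 percentage points (-19.8 to -12.5), of the testis by -12.9 (-16.2 to -9.76), of the heart at 1 year by -15.3 (-19.1 to -11.4) and of the intestine by -19.2 (-22.6 to -16.0), each with an adjusted p of 0.00333. The intestine contrast was the largest, with differences to it of -3.06 points for the heart at 10 months (-5.87 to -0.391, adjusted p = 0.0457, n = 25 chromosomes), -6.25 for the testis (-9.35 to -3.45) and -3.87 for the heart at 1 year (-6.20 to -1.83). The differences of the heart at 10 months to the testis and to the heart at 1 year, and of the testis to the heart at 1 year, did not pass the threshold. The contrasts compared rest on different groups of other tissues and so depend on which tissues were sampled.

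The region names, of which the comparisons above used only the number of loci, showed an irregularity in the 10-month lists. In the brain 80.3% of regions shared their name with another region, in the heart at 10 months 91.8% and in the testis 91.2%, against 0 in the 1-year lists. Super-enhancers whose signal did not match their own length made up 4.97% of the brain list, 20.8% of the heart list at 10 months and 27.4% of the testis list, and 0 in the 1-year lists. Among typical enhancers the percentages were 61.3%, 74.2% and 73.5%. In each 10-month list more regions with a shared name matched than there were shared names. Regions of equal length under 1 name match together, so the percentages that did not match may be too low. No name occurred in both the super-enhancer and the typical-enhancer list of a set, whereas 1000 random labellings of the regions never put fewer than 330 names in both.

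The count of 330 does not weigh for or against a cause, because it only restates that the calls follow the shared names. Equal signal alone would not force equal calls, since the deposited signal did not order these lists. In the brain 1684 typical enhancers carried more signal than the lowest super-enhancer, in the heart at 10 months 1457 and in the testis 2392. Of the 3797 shared names whose regions differ in length, 99.9% had a signal that matched exactly 1 of the lengths, 5 names had more than 1 such length and 0 had none. This is consistent with signal made from 1 region and then looked up by the shared name, a reading that the data had prompted and that was not tested on other data. Regions that were true copies with equal signal are argued against, since 98.1% of the 3870 shared names with a single signal value covered regions of different length. The regions also differed in the other heart list, where 81.5% of the super-enhancers of the heart at 10 months with their own signal were super-enhancers at 1 year, against 44.2% of the 156 without. Shorter length alone does not account for this, because the difference was 31.6 percentage points within length classes (permutation p = 0.0001, the smallest that 10000 permutations can give). Where in the processing the names became shared stays open, and no biological explanation was tested.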

How the results depend on the processing

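The alternatives that kept only super-enhancers with their own signal, redrew them as the longest regions or ranked them by length, and all those of merged regions, were chosen after seeing the data. Of 412 alternative values of the main results, 121 equalled the main value exactly, nearly all because the alternative did not touch the regions concerned, and say nothing about stability. Of the other 291, 256 kept their direction and side of the threshold, or stayed within their interval or 1.5 times the main count, and none reversed. The 20 ordered overlaps passed the threshold under every alternative, including labels drawn among regions of like length, super-enhancers among them, where the excess was 1.16 to 1.65 times. Those length classes were wide, so that alternative does not fully remove length. The brain's lower share in other tissues' enhancers ranged from -3.25 to -5.89 points and stayed past the threshold. Merging regions and keeping numbered chromosomes altered nothing, because no regions overlap and all chromosomes are numbered, nor do alternatives on super-enhancers alter all-enhancer values. The Jaccard difference of the heart pair to the heart at 1 year and the intestine lost significance with the upper part of the lists by signal (3.31) or length (2.47) and with the longest regions (1.32). The share of the heart at 1 year in the other heart minus that in the intestine passed the threshold at -6.35 points under reciprocal overlap, -7.18 with own signal and -5.88 with the longest regions. The own-signal value could only move that way, since of the lists compared only the heart at 10 months lost super-enhancers. These differences make no allowance for the shifted means, which were higher for the intestine. The heart states moved most. Super-enhancers of the heart at 10 months were super, typical or no enhancers in the heart at 1 year in 48.9%, 16.6% and 34.6% under reciprocal overlap, 65.0%, 35.0% and 0% in the upper part by signal, 60.2%, 39.8% and 0% by length, 81.5%, 18.5% and 0% with own signal, and 65.4% and 34.4% (super and typical) as the longest regions. In the other direction the values were 43.1%, 11.5% and 45.4%, then 53.6%, 46.4% and 0%, then 49.6%, 50.4% and 0%, then 54.1% and 45.8% with own signal, and 53.2% and 46.7% as the longest regions. Reciprocal overlap raises the last state by construction, since long regions no longer match short ones; otherwise the cause was not tested. Regions in all 4 tissues fell to 10 in the upper part by signal and 4 by length, which hold fewer regions by construction. No paired analysis was possible because no tissue and age has values per replicate, and for the same reason no replicate was left out. The marker gene alternatives were not run. Depth is unknown, so its effect on the number of regions could not be examined.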

Other observations

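The tests in this part were chosen after the result was seen, except the difference in shares of the heart at 1 year, its reciprocal form and those that made the intestine list as long as the heart list.

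Super-enhancers shared between the hearts, or between the heart at 1 year and the intestine, carried more signal than the others of their list; brain and testis lists were not tested. In the heart at 1 year the median signal was 38502 for super-enhancers that were also super-enhancers in the heart at 10 months and 30899 for the rest (permutation test, adjusted p = 2.4e-05), and signal per base pair was 0.503 and 0.442. In the intestine the medians were 42238 for those shared with the heart at 1 year and 27701 for the rest. Those shared were longer, 66.3 against 43.2 kb (permutation test, adjusted p = 2.4e-05), while signal per base pair was 0.640 and 0.664 (adjusted p = 0.185). In the heart at 10 months, among super-enhancers with their own signal, the medians were 22912 for those shared with the heart at 1 year and 17883 for the rest (permutation test, adjusted p = 0.000189). There too those shared were longer, 55.0 against 40.6 kb, and signal per base pair was 0.432 and 0.437 (permutation test, adjusted p = 0.510).

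Testis super-enhancers were shorter than those of the other lists. Short regions placed in the list by shared names are argued against as the whole cause, since testis super-enhancers with their own signal had a median of 20.8 kb (19.0 to 22.5), below the 52.2 kb of the next lowest list. Fewer loci within joining reach is a candidate explanation: the testis lists held 9.53 loci per Mb against 20.8 to 28.5 in the others, while a testis super-enhancer spanned 7.70 kb per locus, no less than the 6.51 to 7.48 kb elsewhere. A shallower library cannot be told apart from this, because depth is unknown. The ratio of signal to the number in the names, 1.05 times that of the brain, bears on depth only if that number is a read count. Its median was 4.05 in the testis, 3.87 in the brain and 8.97 in the heart at 10 months, the set with 1 library of each kind. What the higher value of that heart means for depth was not tested. A difference of the testis as a tissue stays open and untested.

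The heart at 1 year shared no more super-enhancers with the heart at 10 months than with the intestine. The shifted means were 5.29% for the heart at 10 months and 8.23% for the intestine. Relative to these means the share was 11.5 times in the heart at 10 months and 7.45 times in the intestine. The difference of the shares was -0.471 points, and the intestine share was larger past the threshold under reciprocal overlap (-6.35), with own signal (-7.18) and with the longest regions (-5.88). Shifted means were higher for the intestine there too, 2.86% against 1.71% under reciprocal overlap and 8.84% against 5.58% with the longest regions. Keeping own signal removed super-enhancers only from the heart at 10 months, so it could only lower the share there and decides nothing. Whether a longer intestine list contributes cannot be told apart from a likeness of the lists. Of as many intestine super-enhancers as the heart at 10 months holds, taken by signal, 59.7% were super-enhancers in the heart at 1 year, 14.0 percentage points (11.7 to 16.4) less than the 73.7% of the heart at 10 months, but no choice of as many could have exceeded 71.3%, so the direction was fixed. Reducing the intestine list to the base pairs of the heart list gave a difference of 25.2 points in favour of the heart, and reducing it to the same number of regions 8.82 points (3.98 to 13.3), where removing regions can only lower the intestine share. Loss of true super-enhancers through shared names could not be decided. The difference stayed below 0 (-10.3 to -1.59) with super-enhancers redrawn by length. That redrawing replaced the calls of every list by another definition and kept the number of super-enhancers in each. Likeness of lists prepared together cannot be told apart from likeness of the tissues: the Jaccard index was on average 2.75 points higher with the heart of the same preparation, but by tissue this was 8.04 for the intestine, 2.21 for the testis and -2.02 for the brain.

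In the 10-month lists the number in a region's name may be a size measure of its first locus and not an index. Over regions of a single locus with their own signal, Spearman's rho of that number with signal, across regions that are not independent replicates, was 0.999 in the brain, 0.996 in the heart and 0.999 in the testis, against 0.0603 and 0.0999 in the 1-year lists. A rounded size would give several regions the same name by chance, which was not tested further.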
